A study of Mus musculus with 2 samples.

How the data were processed

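Poly(A)-selected RNA from liver of 8-week-old male B6NCrl mice was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of the same tissue, age and sex. Both formed a single group, adult male liver, so no conditions were compared and every test sets the 2 libraries against each other. The labels describe liver from individual mice and give 2 biosamples but 1 donor identifier, so whether the libraries come from separate animals is not settled. The labels name a size range above 200 for the RNA and a spike-in mix.

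For each library the authors deposited a gene table and a transcript table. Expected counts, estimated reads per gene or transcript that need not be whole, were deposited by the authors without normalisation. TPM and FPKM, both scaled by the authors for length and library size, were deposited beside the counts, per the file headers. The transcript tables also hold, per the file headers, the percent of each gene's expression on each transcript, and all tables hold a posterior SD of the count. The accompanying descriptions name the mm10 assembly and annotation M4; the aligner, the quantification program and their versions are not given in the sources used here. The effective length was 35 bases below the length in 100% of the gene rows longer than that, an inference from the values. Reads shared between near-identical genes are divided by such estimates, so values of paralogs, pseudogenes and multigene families, among them the Mup, Serpina1, Hba-a1 and Hba-a2, Saa, Cyp2c, Cyp3a, Cyp4a12 and Hspa1a and Hspa1b genes, can be split between copies. Without a stated strand setting, genes and overlapping antisense genes cannot be told apart.

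The gene tables have 69691 rows: 43346 mouse genes, 26248 rows with a numeric identifier, 96 spike-in rows and 1 phage row. Names, types and coordinates were taken from GENCODE M21 on GRCm38, the same assembly with a later annotation, by identifier without version; 42462 mouse genes matched and 884 did not, and these keep their identifiers. GC content was that of the most abundant transcript of each gene with a sequence in that annotation. Numeric, spike-in and phage rows were left out of library sizes and tests.

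Expected counts were rounded to whole numbers, 10413363 in replicate 1 and 7824979 in replicate 2 over mouse genes, so a count of 3, the limit that a count of 0 allows, stands for 0.288 and 0.383 CPM. Libraries were scaled with edgeR 4.0.16 in R 4.3.3 by trimmed mean of M values (factors 0.873 and 1.15), and the common dispersion was estimated with an intercept alone. The 13109 genes with a mean CPM of at least 1 were tested with the exact binomial test in edgeR, two-sided and conditional on the summed count, with a chi-square approximation for very large counts. They were called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold, with log2 ratios from CPM with a prior count of 2. Printed folds are ratios of scaled counts, and counting intervals are exact 95% Clopper-Pearson intervals turned into ratios. PCR reads are not independent molecules, and a called gene differs between these libraries only.

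There were 50 gene lists. For lists with at least 5 tested members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The genes named were the 20 with the highest mean TPM; up to 4 members with the highest mean TPM and up to 3 called members with the largest ratio of each list; the 10 called genes with the largest ratio in each direction with a mean TPM of at least 1; all genes of the sex-chromosome list; and any member of the urea cycle, bile acid synthesis, circadian, alpha-1-antitrypsin and transcription factor lists. Correlations used log2(TPM + 1) over genes with a mean TPM of at least 1. The most abundant transcript of each gene was compared for genes with a TPM of at least 1 in both libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for the figures.

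The tests were tried on simulated counts for the 13109 genes, with 200 changed genes. With a coefficient of variation of 0.1, 64.5% of 2-fold and 91.5% of 4-fold changes were recovered. In the 2-fold simulation 0.279% of unchanged genes were called. With a coefficient of 0.3 these values were 60%, 85.5% and 12.5%. Recovery required an adjusted p under 0.05 and the right direction, but for 2-fold changes a fold minimum below that of a call. The median log2 ratio of genes raised 2-fold was 0.94 and 0.86, under the 2-fold minimum, so fewer would be called than were recovered. The list step found 5 of 5 shifted lists among 45, with 1 other list apart. In that trial every member of a shifted list was raised 4-fold, and genes varied independently. This shift is larger than any list median found here, so the trial does not show how well smaller shifts are found. With the GC trend removed, 87.5% of 4-fold changes were recovered among 13046 genes.

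The alternatives were DESeq2 1.42.0 size factors, total counts, the ratio of TPM values, other minimums for TPM, CPM, fold and pseudocount, Fisher's exact test, leaving out mitochondrial and the most abundant genes, leaving out each replicate, list means and matching on gene length. Chosen after seeing the data were nuclear protein-coding genes alone, genes with a posterior SD of at most 5% of the count, detection of protein-coding genes alone, random lists matched on GC content, the sex-linked check in each library alone, and removal of the trend of the log2 ratio on GC content, interpolated over the medians of 20 GC bins of nuclear protein-coding genes.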

Results

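Poly(A)-selected RNA was sequenced from the livers of 8-week-old male mice of the strain B6NCrl, a C57BL/6 substrain. The 2 libraries, numbered replicates 1 and 2 in the labels, formed a single group of adult male liver, so the study gave a reference profile of the tissue and no contrast between conditions. The labels gave the libraries separate biosamples from individual animals but the same donor identifier, so the spread between them measures only these 2 samples and part of it may be technical. Mouse genes received 10413431 expected counts in replicate 1 and 7824998 in replicate 2. A gene at 0 counts could have had a share of up to 0.288 CPM (counts scaled to library size) in replicate 1 and 0.383 in replicate 2, from the floor of 3 counts. Levels are given as mean ± SD of transcript abundance scaled by length and library (TPM), n = 2. Fold differences are ratios of normalised counts of replicate 2 to replicate 1. The floors and the intervals of folds and of shares of counts cover counting error only. The interval for a share of genes and the bootstrap intervals are instead over genes, which are not independent replicates. The words higher and lower, used of a gene between the replicates, refer to the exact binomial test between the 2 libraries with at least a 2-fold difference. A gene that did not pass missed the adjusted p, the 2-fold minimum or both, so smaller differences beyond counting error remain possible for it. This test compares the libraries and not conditions. The gene lists, the main tests and the rule for naming genes were set before the data were examined. Values for nuclear protein-coding genes alone, for genes little affected by shared reads, with the GC trend removed and against random lists matched on GC content were added after the data were seen.

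Nuclear protein-coding genes held 51.4% of the expected counts in replicate 1 (95% Clopper-Pearson interval 51.4 to 51.4%) and 61.5% in replicate 2 (61.5 to 61.6%). Mitochondrially encoded genes held 28.1% (28.1 to 28.1%) and 12.6% (12.6 to 12.6%). The row ENSMUSG00000045999.9, to which the annotation used here gave no name, held 8.55% and 10.5%. Gm42418 (chromosome 17, 39846958 to 39848788, GRCm38), a long intergenic non-coding RNA in the GENCODE annotation whose locus RefSeq lists as the ribosomal RNA-related pseudogene Rn18s-rs5, held 6.06% and 10.1%. A TPM of at least 1 in both libraries was reached by 10948 genes, of which 9642 were protein-coding.

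**Figure D1:**
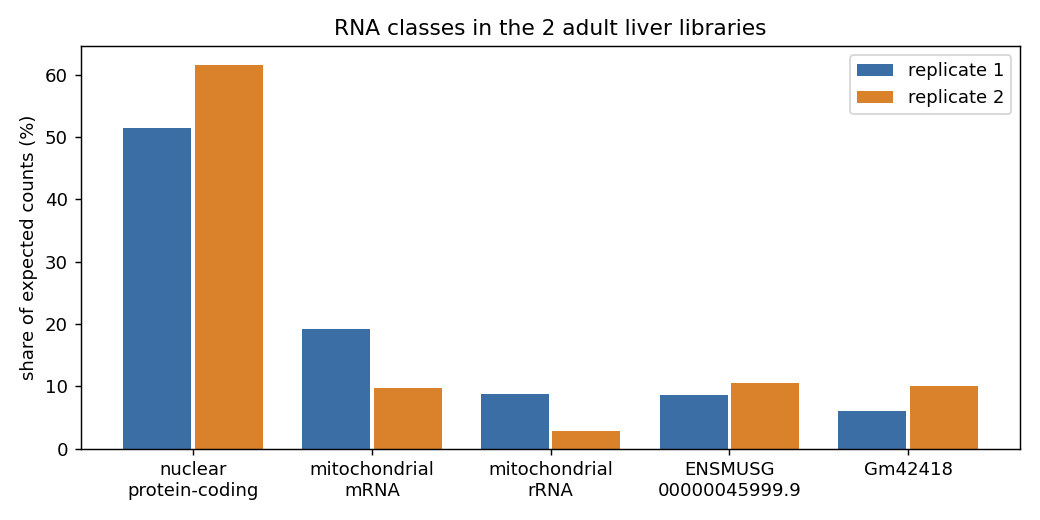
Share of all expected counts (%, linear axis from 0) in 5 classes of RNA in replicate 1 (blue) and replicate 2 (orange); each bar is 1 library. Nuclear protein-coding genes held 51.4% and 61.5%, and mitochondrial mRNA held 19.1% and 9.67%.

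The 10 most abundant genes held 31.8 ± 1.29% of the TPM of mouse genes, and the top 100 held 72.8 ± 7.60%. Highest in mean level were ENSMUSG00000045999.9 (79002 ± 12754 TPM), Gm42418 (47336 ± 17402 TPM) and the 123-nt Mir6236 (29945 ± 26264 TPM). TPM is divided by length, so short rows rank high in it. In expected counts Mir6236 had 10039 and 31418, against 233896 and 242053 for albumin. ENSMUSG00000089855.1, mt-Ts1 and Snord104, named below, are likewise short, at 159, 69 and 70 bases. Of the 20 highest rows, 11 were mitochondrially encoded. They were led by the large ribosomal RNA mt-Rnr2 (26870 ± 21436 TPM) and the cytochrome oxidase subunits mt-Co2 (25887 ± 9066 TPM), mt-Co1 (24845 ± 9361 TPM) and mt-Co3 (22949 ± 10015 TPM). The others of these 11 were mt-Rnr1, mt-Ts1, mt-Atp6, mt-Cytb, mt-Atp8, mt-Nd3 and mt-Nd1. The chromosome 1 pseudogene Gm10925 (18123 ± 1210 TPM) resembles mitochondrial sequence and can share its reads. The remaining rows were the major urinary proteins Mup7 (16092 ± 7763 TPM) and Mup14 (15063 ± 7822 TPM), albumin (Alb, 13997 ± 3371 TPM; chromosome 5, 90460897 to 90476602), the unnamed ENSMUSG00000089855.1 (18589 ± 4098 TPM) and the small nucleolar RNA Snord104, whose mean came almost wholly from replicate 2 (59.8 and 20741 TPM).

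Secreted proteins of hepatocytes were expressed at high levels in both libraries. All 28 genes of the plasma protein list were detected, with a summed level of 37054 ± 11117 TPM. Besides Alb, the highest in TPM were the iron carrier transferrin (Trf, 4842 ± 2527 TPM), the serine protease inhibitor Serpina3k (4244 ± 80.5 TPM) and fetuin-A (Ahsg, 2178 ± 1245 TPM). In expected counts Serpina3k exceeded Trf in both libraries (87228 and 62304 against 33536 and 46172). A transcript of 433 bases held 66.0% and 53.9% of the TPM of Trf. Serpina6, corticosteroid-binding globulin, was the 1 member that passed, 2.30-fold (95% counting interval 2.06 to 2.58) higher in replicate 2. The 15 of 15 apolipoprotein and lipoprotein-assembly genes detected summed to 30755 ± 11409 TPM, led by Apoa2 (9232 ± 3385), Apoe (5881 ± 2956), Apoc1 (5802 ± 1523) and Apoa1 (3711 ± 1532). Apom and Pltp were higher in replicate 2, by 3.26-fold and 2.95-fold; the other 13 did not pass. The 5 alpha-1-antitrypsin paralogs, led by Serpina1e (4948 ± 756 TPM), summed to 12959 ± 3449 TPM, and none passed; reads may be split between these copies.

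Coagulation factors and inhibitors (19 of 19 detected) summed to 3941 ± 817 TPM, with Serpinc1, which encodes antithrombin, at 803 ± 229 TPM and the fibrinogen chains Fga, Fgg and Fgb at 513 ± 73.4, 511 ± 70.2 and 474 ± 28.9. F7 was 2.09-fold higher in replicate 2. Complement genes (19 of 19 detected) summed to 4886 ± 378 TPM, led by C3 (1477 ± 444 TPM) and C9 (823 ± 328 TPM). A transcript of 315 bases held 70.5% and 64.6% of the TPM of C3. For C9, a transcript of 543 bases held 84.4% and 77.9%. C9 was 2.20-fold lower in replicate 2; with the GC trend removed, 1 complement gene was higher and none lower. Of the acute-phase list, 16 of 19 were detected (4478 ± 2621 TPM). The iron hormone hepcidin, Hamp, was 5.38-fold (95% counting interval 5.10 to 5.68) higher in replicate 2 (448 and 3241 TPM), and its paralog Hamp2 was 7.76-fold higher. Haptoglobin (Hp, 1298 ± 477 TPM) and Orm1 (628 ± 137 TPM) did not pass, and 2 of 16 tested members, among them Fgl1 (2.18-fold), were lower. The iron and heme list (18 of 18, 12880 ± 6233 TPM) included the ferritin chains Ftl1 (2484 ± 1146 TPM) and Fth1 (1179 ± 281 TPM), and Hamp was the 1 of its 18 members that passed, joined without the GC trend by 1 lower member. C9 and Fgl1 did not pass with scaling by total counts, the TPM ratio or both, and F7, C9 and Fgl1 did not pass with the GC trend removed.

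The major urinary proteins, a pheromone-carrier family made by male liver, were mostly lower in replicate 2. Their summed level was 101638 TPM in replicate 1 and 51629 TPM in replicate 2, and 14 of 21 tested members were lower and 3 higher. Mup7 and Mup14 were 2.71-fold and 2.90-fold lower, Mup3 (9592 ± 1571 TPM) did not pass, and Mup9 was 2.11-fold higher. Mup15 was listed at 0 in replicate 2 and at least 11681-fold lower against the floor of 3 counts per library, with a counting interval from 9499, while Mup19 and Mup8 were 52.7-fold and 40.1-fold lower. These near-identical genes share reads, so single members are uncertain. The median log2 ratio was -1.54, below all 10000 random lists. With the GC trend removed it was -0.89, still below all of them, and 8 members were lower. Mup9 did not pass with scaling by total counts, the TPM ratio or both, and Mup7 and Mup14 did not pass with the GC trend removed.

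The list of genes known to be higher in male liver had a median shifted towards replicate 1, and the list of genes known to be higher in female liver had a median shifted towards replicate 2. Of the 17 male-biased genes tested, 5 were lower and none higher (median log2 ratio -0.64, percentile 0.09 of random lists). They included Mup20 (4.40-fold (95% counting interval 4.31 to 4.49)), the fatty-acid elongase Elovl3 (3.11-fold (95% counting interval 2.78 to 3.50)) and Selenbp2 (2.33-fold (95% counting interval 2.21 to 2.46)). Of 11 female-biased genes tested, 5 were higher and none lower (median 0.90, percentile 99.99). Cyp2a4 was at 1.61 and 53.7 TPM, Hamp2 at 16.4 and 171 TPM, and Cyp2b9, listed at 0 in replicate 1, was at least 7.78-fold higher against the floor of 3 counts, with a counting interval from 5.83. Reads may be split between Cyp2a4 and other Cyp2a genes, and between Hamp2 and its paralog Hamp, which was also higher. With the GC trend removed, 3 male-biased genes were lower and 8 female-biased genes higher. The list levels summed to 12664 ± 1219 TPM for the male-biased genes (16 of 18 detected) and 536 ± 328 TPM for the female-biased genes (9 of 23 detected). Selenbp2 did not pass with scaling by total counts, the TPM ratio or both.

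**Figure D2:**
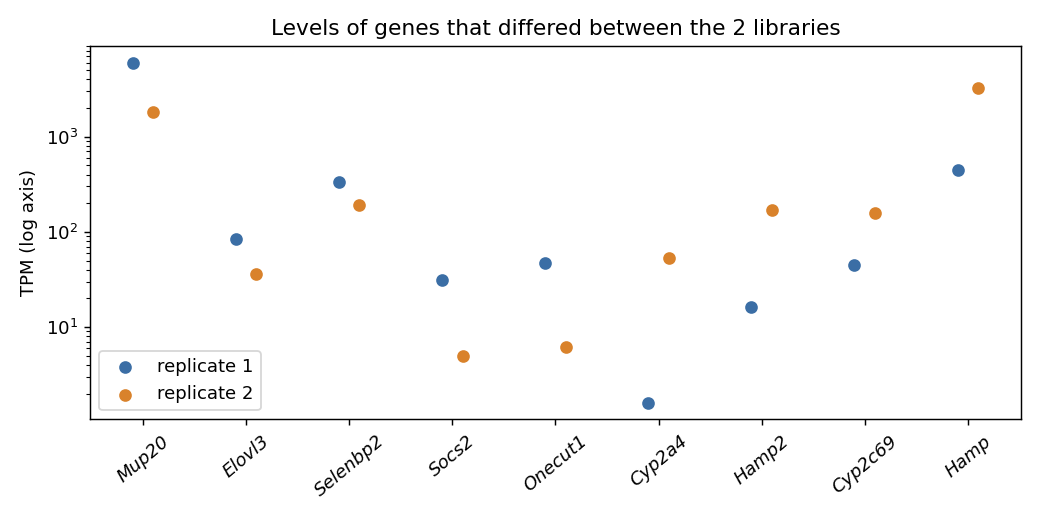
TPM (log axis) of 9 genes in replicate 1 (blue) and replicate 2 (orange); each point is 1 library. Mup20, Elovl3, Selenbp2, Onecut1 and Socs2, the last chosen after its values were seen, lie lower in replicate 2, and Cyp2a4, Hamp2, Cyp2c69 and Hamp lie higher. Cyp2a4, for example, lies at 1.61 and 53.7 TPM. Mup20, Cyp2a4, Cyp2c69, Hamp and Hamp2 can share reads with paralogs.

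Y-linked genes were expressed in both libraries, and Xist was close to 0 in both, as a check of the labelled male sex. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at 13.2 ± 0.438, 10.98 ± 1.65, 6.11 ± 1.95 and 4.94 ± 0.495 TPM, summing to 35.2 ± 2.67 TPM. Xist, the RNA that coats the inactive X chromosome of females, had 4 and 1 counts, and Tsix was listed at 0. Uty was 2.36-fold lower in replicate 2. Uty did not pass with scaling by total counts, the TPM ratio or both, nor with the GC trend removed.

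The lists of gluconeogenesis and cholesterol synthesis genes had medians above those of random lists, whereas the shift of the lipogenesis list (percentile 99.54) depended on how GC content was treated. Its percentile was 97.8 with the GC trend removed, still outside the random range, and 89.7, inside it, against random lists matched on GC content. Of 15 gluconeogenesis genes tested, 5 were higher and 1 lower (median log2 ratio 0.57, percentile 99.85; 14 of 15 detected, 4767 ± 329 TPM). The tyrosine aminotransferase Tat was 3.26-fold (95% counting interval 3.11 to 3.43) higher, Fbp1 2.25-fold and Gpt 2.59-fold, whereas the coactivator Ppargc1a was 2.77-fold lower; Aldob (3076 ± 634 TPM) and Pck1 (694 ± 326 TPM) did not pass. After removal of the GC trend, 2 members were higher and none lower. Of 25 cholesterol synthesis genes, 6 were higher and none lower (median 0.47, percentile 99.96; 1316 ± 548 TPM), among them Fdps (2.45-fold), Pmvk (3.25-fold), Mvd (3.15-fold) and Mvk (2.63-fold). Insig1, Ebp and Sc5d, at 142 ± 38.1, 114 ± 36.2 and 111 ± 37.2 TPM, did not pass. Once corrected for GC content, 3 of the 25 were higher. In the lipogenesis list (20 of 21, 3086 ± 739.6 TPM) Srebf1, the transcription factor of fatty-acid synthesis, was 4.08-fold (95% counting interval 3.57 to 4.68) higher and Fasn 2.07-fold higher. The other 18 members tested did not pass, with Scd1 at 891 ± 104 TPM, Thrsp at 407 ± 94.5 TPM, Khk at 329 ± 198 TPM and Tkfc at 216 ± 83.3 TPM. Without the GC trend, 1 of the 20 was higher. Ppargc1a did not pass with scaling by total counts, the TPM ratio or both, and Ppargc1a, Gpt, Mvk and Fasn did not pass with the GC trend removed.

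The list of PPARα and fasting targets (31 of 34, 9057 ± 578 TPM) was led by the fatty-acid binding protein Fabp1 (6901 ± 30.4 TPM), Acox1 (416 ± 137 TPM) and Hmgcs2 (354 ± 25.1 TPM). Of its 34 genes, 5 were higher in replicate 2, including Acot3 (12.7-fold (95% counting interval 4.66 to 48.4)), Acot1 (3.33-fold), Hmgcl (2.24-fold) and Acaa1b (2.09-fold), and none lower; with the GC trend removed 5 were higher, although Hmgcl and Acaa1b no longer passed. The 8 urea cycle genes summed to 1829 ± 575 TPM: Ass1 was at 702 ± 350.1 TPM, Arg1 at 477 ± 33.3 TPM, Cps1 at 249 ± 29.7 TPM, Asl at 228 ± 159.8 TPM and Otc at 76.2 ± 24.99 TPM. Otc was 2.14-fold lower in replicate 2 and did not pass once the GC trend was removed. Nags, Slc25a15 and Slc25a13 were at 9.08 ± 4.86, 47.98 ± 14.1 and 39.6 ± 8.20 TPM. The amino-acid metabolism list (36 of 36, 4383 ± 1024 TPM) was led by Hpd (568 ± 262 TPM), Mat1a (417 ± 137 TPM), Bhmt (377 ± 17.5 TPM) and Tdo2 (298 ± 1.69 TPM). Otc and Cth (2.21-fold) were its 2 lower members of 36, and neither passed without the GC trend. Otc and Cth did not pass with scaling by total counts, the TPM ratio or both, and Acaa1b, Hmgcl, Otc and Cth did not pass with the GC trend removed.

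All 16 genes of bile acid synthesis were detected (3174 ± 632 TPM). Cyp7a1, the rate-limiting enzyme, was at 29.3 ± 6.64 TPM and did not pass. Cyp27a1 was 2.59-fold (95% counting interval 2.42 to 2.77) higher in replicate 2 and Cyp7b1 2.11-fold (95% counting interval 1.88 to 2.38) lower, the latter not passing without the GC trend, when 2 members were higher and none lower. Scp2 (1237 ± 30.3), Slc27a5 (405 ± 263), Slc27a2 (313 ± 8.37), Akr1c6 (312 ± 65.1), Cyp8b1 (103 ± 63.3) and Cyp2c70 (161 ± 2.74) did not pass. Bile transporters (16 of 16, 1052 ± 169.95 TPM) included the export pump Abcb11 (217 ± 5.38 TPM), the uptake carrier Slc10a1 (169.7 ± 51.7 TPM), Abcc2 (138 ± 47.2 TPM) and Slco1b2 (133 ± 33.9 TPM). Of 16 tested, 2 were higher and 2 lower: Abcg2 was 2.24-fold lower, Slco1b2 2.003-fold lower and Slco1a4 2.30-fold higher. Without the GC trend 1 was higher and none lower. Cyp7b1, Abcg2 and Slco1b2 did not pass with scaling by total counts, the TPM ratio or both, nor with the GC trend removed.

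The cytochrome P450 list had a median shifted towards replicate 2. Of 43 tested, 6 were higher and none lower, with a median log2 ratio of 0.39 (percentile 99.99; 40 of 51 detected, 5198 ± 1515 TPM). Cyp2a4 was 24.99-fold (95% counting interval 17.02 to 38.2) higher and Cyp2c69 2.58-fold; members of the Cyp2a, Cyp2c and Cyp3a families can share reads. The highest members, Cyp2e1 (639.9 ± 236 TPM), Cyp3a11 (416 ± 39.9 TPM), Cyp2d9 (375 ± 166 TPM) and Cyp2a5 (367 ± 251 TPM), did not pass. Without the GC trend, 9 were higher. Conjugation enzymes (35 of 36, 9174 ± 2001 TPM) were led by Gstp1 (2404 ± 1028 TPM), Mgst1 (2377 ± 384 TPM), Gstm1 (944 ± 477 TPM) and Gsta3 (595 ± 313 TPM). Of 36, 4 were higher, among them Gnmt (3.33-fold), and 5 lower, among them Ugt2b1 (3.16-fold) and Gstp2 (3.27-fold, sharing reads with Gstp1); without the GC trend 4 were higher and 1 lower. The alcohol, aldehyde and carboxylesterase list (25 genes, all detected, 3504 ± 1298 TPM) held Ces3a (615 ± 240.1 TPM), Adh1 (542 ± 305 TPM), Ces1c (524 ± 169 TPM) and Ces3b (242 ± 99.97 TPM). Ces1d was 2.53-fold higher and Ces3b 2.31-fold lower. Ces3b did not pass with scaling by total counts, the TPM ratio or both, and Ugt2b1 did not pass with the GC trend removed.

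Hepatocyte transcription factors were detected for 31 of 32 genes (1113 ± 407 TPM). Onecut1 (hepatocyte nuclear factor 6) was 9.998-fold (95% counting interval 8.46 to 11.9) lower in replicate 2 at 47.2 and 6.17 TPM, and Cebpb, Foxa1 and Foxa2 were 2.38-fold, 2.54-fold and 2.10-fold lower. Ppargc1a made 5 lower of 32. Nr1i3, the constitutive androstane receptor, was the 1 higher member (2.95-fold). Hnf4a (104 ± 10.5 TPM), Atf5 (251 ± 148 TPM), Creb3l3 (84.5 ± 35.5 TPM), Cebpa (81.5 ± 12.4 TPM), Rxra (69.9 ± 47.7 TPM) and Hnf1a (12.3 ± 7.68 TPM) did not pass. Without the GC trend 4 were lower and 3 higher. Cebpb, Foxa1, Foxa2 and Ppargc1a did not pass with scaling by total counts, the TPM ratio or both, and Ppargc1a did not pass with the GC trend removed.

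The list of circadian clock genes whose liver transcripts peak in the light phase had a median shifted towards replicate 2, with 3 of 10 members higher and none lower. The 10 genes of this list had a median log2 ratio of 0.73 (percentile 99.92; 9 of 10 detected, 255 ± 119.97 TPM), and Ciart (3.85-fold (95% counting interval 2.80 to 5.39)), Per3 (2.67-fold (95% counting interval 2.30 to 3.10)) and Usp2 (2.41-fold (95% counting interval 2.02 to 2.89)) were higher. Tef (80.6 ± 39.4), Dbp (61.7 ± 26.2), Nr1d1 (24.9 ± 9.46), Hlf (17.7 ± 8.39), Per1 (12.5 ± 7.71), Nr1d2 (17.5 ± 2.26) and Bhlhe41 (1.79 ± 1.24) did not pass. Of 7 tested genes of the night list (6 of 8 detected, 40.5 ± 23.4 TPM), Rorc, Cry2 and Per2 were 2.32-fold, 2.12-fold and 2.30-fold higher, and none passed without the GC trend. Arntl had 12 and 7 counts, and Npas2 2 and 0. Usp2 did not pass with the GC trend removed.

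Markers of both lobule zones were expressed. The pericentral list (19 of 22, 2650 ± 717 TPM) held Rgn (321 ± 47.8 TPM) and glutamine synthetase (Glul, 255 ± 88.1 TPM), with 2 of 22 higher in replicate 2 (Rnf43, 3.55-fold, and Axin2, 2.33-fold) and Lgr5 2.45-fold lower. The periportal list (21 genes, all detected, 3516 ± 1445 TPM) had a median log2 ratio of 0.35 (percentile 99.04), and Ifitm3 was its 1 called member (2.19-fold higher); without the GC trend none passed and the percentile was 96.9. Axin2 and Lgr5 did not pass with scaling by total counts, the TPM ratio or both, and Axin2 did not pass with the GC trend removed.

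Other liver cell types contributed low but measurable RNA. Kupffer cell and macrophage markers (17 of 17) summed to 248 ± 51.1 TPM, led by Clec4f (47.3 ± 15.6 TPM), and Ctss was the 1 of 17 that passed (2.12-fold lower). Sinusoidal endothelial markers (20 of 21, 204 ± 62.1 TPM) included Egfl7 (34.8 ± 18.5 TPM), Stab1 (27.9 ± 8.31 TPM) and Clec4g (27.02 ± 10.7 TPM), and none passed. A transcript of 242 bases held 60.4% and 36.0% of the TPM of Stab1. Stellate cell and fibroblast markers (14 of 19, 149.8 ± 9.11 TPM) were led by Ecm1 (63.9 ± 2.08 TPM) and Dcn (25.3 ± 8.32 TPM); of 19, Myh11 was 3.04-fold higher and Dcn 2.18-fold lower. Ctss, Myh11 and Dcn did not pass with scaling by total counts, the TPM ratio or both, nor with the GC trend removed. Cholangiocyte markers (3 of 13, 26.3 ± 3.73 TPM), led by Spp1 (16.8 ± 0.163 TPM), and lymphocyte markers (4 of 18, 17.2 ± 6.08 TPM), led by Igkc (5.74 ± 3.22 TPM), had no member that passed. Neutrophil markers (0 of 15 detected, 3.69 ± 0.544 TPM), pancreatic markers (1 of 26, 8.40 ± 3.30 TPM) and markers of other tissues (4 of 25, 63.1 ± 12.8 TPM) were low, the last led by Fabp2 (30.8 ± 2.32 TPM) and Lgals4 (23.9 ± 11.7 TPM).

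Red-cell transcripts had a list median shifted towards replicate 1. Of 7 erythroid genes tested, 4 were lower and none higher (median log2 ratio -1.50, percentile 0.02; 6 of 9 detected, 1349 ± 493 TPM). The globins Hbb-bt and Hbb-bs were 4.42-fold (95% counting interval 3.82 to 5.13) and 2.83-fold (95% counting interval 2.62 to 3.05) lower, and Hba-a1 3.57-fold, although the near-identical Hba-a2 (573 ± 52.5 TPM) did not pass and the pair can share reads. Snca was 5.63-fold lower. Without the GC trend 5 were lower, while among genes with a posterior SD of at most 5% of the count the percentile was 4.58, inside the random range.

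Of 12 immediate-early genes tested (12 of 22 detected, 88.6 ± 24.7 TPM), 3 were higher, including Junb (2.54-fold) and Jund (2.08-fold), and 3 lower, including Myc (4.34-fold (95% counting interval 2.79 to 6.99)) and Egr1 (2.31-fold (95% counting interval 1.64 to 3.30)). Without the GC trend none was higher and 4 were lower. Heat-shock genes (13 of 14, 1587 ± 44.7 TPM) had 3 lower of 13, Hsp90aa1 (2.17-fold), Hspa4l (2.23-fold) and Hspa1b (2.26-fold), of which 1 passed without the GC trend; the list median was -0.21 (percentile 19.5) and with that trend removed -0.36, outside the random range (percentile 1.05). None of the 21 genes of endoplasmic reticulum stress (1772 ± 261 TPM, led by Calr, 455 ± 6.05 TPM) or the 13 tested genes of oxidative stress (12 of 15, 1226 ± 541 TPM) passed; without the GC trend 1 endoplasmic reticulum stress gene was lower. Interferon genes (21 of 27, 214 ± 8.92 TPM) had 1 higher of 26, Oasl1 (5.19-fold), and 2 lower, Iigp1 (3.02-fold) and Ifi44 (2.69-fold), neither of the lower ones passing without the GC trend. In the glucocorticoid list (10 of 14, 572 ± 324 TPM) Tat was the 1 of 12 that passed. Proliferation genes were low (4 of 20, 25.7 ± 5.14 TPM) and none of 10 passed. The fetal liver list (1 of 10, 8.29 ± 2.84 TPM) had Gpc3 as 1 higher of 4; with p-values adjusted over the list alone it had none. Myc, Egr1, Hsp90aa1, Hspa4l, Hspa1b, Ifi44 and Gpc3 did not pass with scaling by total counts, the TPM ratio or both, and Junb, Jund, Hsp90aa1, Hspa4l, Iigp1 and Ifi44 did not pass with the GC trend removed. For the other 49 lists, the counts adjusted over the list alone equalled those over all genes.

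Mitochondrially encoded mRNA and rRNA were mostly lower in replicate 2. Of the 15 genes, 14 were lower and none higher, with a median log2 ratio of -1.50, below all 10000 random lists, and a summed level of 224079 ± 121469 TPM. The largest differences were mt-Atp6 (6.65-fold), mt-Atp8 (4.83-fold) and mt-Rnr2 (4.82-fold). For 3 members, among them mt-Atp6, the posterior SD exceeded 5% of the count in at least 1 library, so reads shared with nuclear copies can move them. These genes have a median GC content of 35.98%, below the median of 38.9% in the lowest GC bin of nuclear protein-coding genes. Below that bin the trend was held at the bin's log2 ratio of -0.75. With the trend removed in this way the list median was -0.74 and 4 were lower. Any further effect of a GC content below that bin was not removed, so these values are not free of GC content. Nuclear genes of oxidative phosphorylation (45, all detected, 7302 ± 1291 TPM) had a median of -0.06, inside the random range, with 2 lower, Cox6c (2.27-fold) and Uqcrb (2.54-fold). Ribosomal protein genes (71, all detected, 13972 ± 4183 TPM) had a median of 0.27 (percentile 99.98), with 7 higher, including Rps27 and Rps23 (5.11-fold and 4.75-fold), and 3 lower, including Rpl39 (3.26-fold); for 13 members, among them Rps27 and Rps23, the posterior SD of the estimated count exceeded 5% of it, so reads shared with copies can move them. mt-Co1, mt-Co2, mt-Co3, Cox6c and Uqcrb did not pass with scaling by total counts, the TPM ratio or both, and mt-Co1, mt-Co2, mt-Co3 and Uqcrb did not pass with the GC trend removed. Housekeeping genes (17, all detected, 4432 ± 790.1 TPM) had no member that passed, with Actb at 387 ± 18.8 TPM and B2m at 1946 ± 118 TPM.

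Most small nucleolar RNAs and all tested small nuclear RNAs and nuclear rRNA genes were higher in replicate 2. Of 107 small nucleolar RNAs tested, 90 were higher and 4 lower, with a median log2 ratio of 3.65, and all 27 small nuclear RNAs and all 10 nuclear rRNA genes tested were higher. Of 9 small Cajal body RNAs tested, 5 were higher and 1 lower (median 1.10), of 16 genes annotated as miscellaneous RNA 5 were higher and 2 lower (median 0.60), and of 15 microRNA genes 7 were higher and 4 lower (median 0.28). Mitochondrial transfer RNAs, by contrast, had 2 higher and 15 lower of 22 (median -2.08). Small nucleolar RNAs held 0.0311% of the counts in replicate 1 (0.0300 to 0.0322%) and 0.317% in replicate 2 (0.313 to 0.321%). In TPM, which is divided by length, they held 0.290% and 6.75%. The list of RNAs without a poly(A) tail (9 of 16 detected, 13400 ± 3504 TPM) had 3 higher of 11, Rnu12 (0.5 and 154 counts), Rnu11 and Snord118 (5.13-fold), while Rn7s1, Rn7s2, Rn7sk and Rpph1 did not pass. The nuclear long RNAs (1862 ± 431 TPM), among them Malat1 (1665 ± 325 TPM) and Neat1 (191 ± 106 TPM), did not pass, and 1 of 5 was lower with the GC trend removed.

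The counts of the 2 libraries were not the same within counting error, with a chi-square statistic per degree of freedom of 123, and they were kept as 2 samples. Across 12466 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.860 and Spearman's rho 0.832; over nuclear protein-coding genes r was 0.942. edgeR's biological coefficient of variation was 38.4%, or 30.1% over nuclear protein-coding genes. Of 13109 genes tested, 967 were higher in replicate 2 and 877 lower; for 640 of these 1844 genes the posterior SD of the estimated count exceeded 5% of it in at least 1 library, or the count was 0. The calls were 14.1% of the genes tested. In counts simulated with a coefficient of variation of 0.3 between the libraries, 12.5% of unchanged genes were called. That coefficient lies under the 38.4% estimated here, and no simulation was run at 38.4%. The 2 shares therefore cannot show whether more genes were called than such a spread alone would give. The split depended on scaling: by total counts, 2213 were higher and 347 lower, and by TPM ratio 1585 and 215, with medians of all genes of 0.38 and 0.34 on the log2 scale against 0.02 under the main scaling.

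The log2 ratio rose with GC content. Over 11451 nuclear protein-coding genes with a GC value, Spearman's rho between the 2 was 0.624 across genes, and the median log2 ratio ran from -0.75 in the lowest of 20 GC bins to 0.55 in the highest. Removing this trend, an alternative chosen after seeing the data, left 1057 genes that passed, 634 higher and 423 lower, of which 880 were among the 1844.

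**Figure D3:**
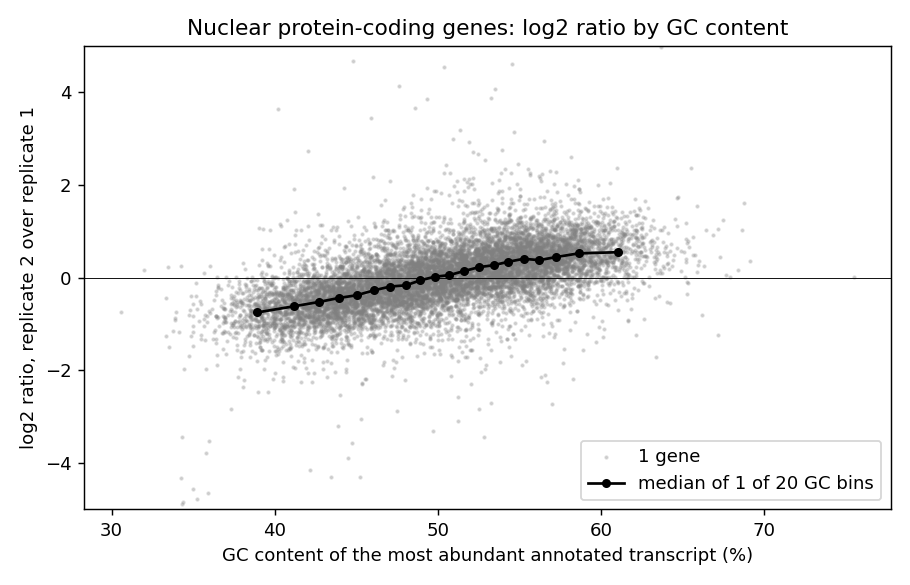
Log2 ratio of replicate 2 over replicate 1 against the GC content (%) of each gene's most abundant annotated transcript; grey points are nuclear protein-coding genes and black points the medians of 20 GC bins. The medians run from -0.75 to 0.55; 6 of 11451 genes lie beyond the vertical axis limits of -5 and 5.

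The genes with the largest differences were mostly small RNAs and members of families that share reads. The 10 highest in replicate 2 were Snord14d, Snord14c, Snord104, Snord32a and Snord49b, together with Snord49a, Gm7536, Gm22513, Gm3362 and Gm15501, which were listed at 0 in replicate 1. Snord104 (chromosome 11, 106500993 to 106501062) was 258-fold (95% counting interval 169 to 417) higher. Snord49b, with 1 and 324 counts, had a ratio of 329 with a wide counting interval of 58.6 to 13024. The 10 lowest were Mup15, Mup19, Mup8, Gm26377, Rps24-ps2, ENSMUSG00000065950.1, Gm7308, Rpl6l, Gm12191 and Gm13772, all listed at 0 in replicate 2 except Mup19 and Mup8. Gm26377 and Rps24-ps2 were at least 474-fold and at least 311-fold lower against the floor, with counting intervals from 385 and 252. A value of 0 here can come from how shared reads were assigned. A further selection, made after the values were seen, took nuclear protein-coding genes with a posterior SD of at most 5% of the count. Among these, Hamp (5.38-fold), Oasl1 (5.19-fold) and Lrfn4 (5.68-fold) were among the 10 highest in replicate 2. Gm10800 (25.2-fold), Onecut1 (9.998-fold), Socs2 (8.48-fold) and Camk2a (8.38-fold) were among the 10 lowest.

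Of 45 lists with at least 5 tested genes, 15 had a median log2 ratio outside the central 95% of random lists, 11 above and 4 below. Lists of unrelated genes would give 2.25 on average. Some lists share members, such as Cyp2a4 in the cytochrome P450 and female-biased lists and Mup20 in the major urinary protein and male-biased lists. The 15 shifts are therefore not independent. Besides those described, the plasma protein (percentile 99.61), apolipoprotein (97.8), lipogenesis (99.54) and alcohol and aldehyde (99.02) lists lay above. After GC correction 14 lists lay outside, 13 of them the same; the apolipoprotein list was at 80.03 and the heat-shock list was added. Against random lists matched on GC content, 15 lay outside, 11 of them the same. The lipogenesis, apolipoprotein, periportal and ribosomal protein lists were then inside the random range, at percentiles 89.7, 67.05, 97.3 and 97.2; of these, the lipogenesis and ribosomal protein lists stayed outside it with the GC trend removed, at 97.8 and 99.51. Bile transport, pericentral and conjugation genes lay above the range with GC matching and immediate-early genes below, at 99.1, 98.3, 97.7 and 0.02.

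**Figure D4:**
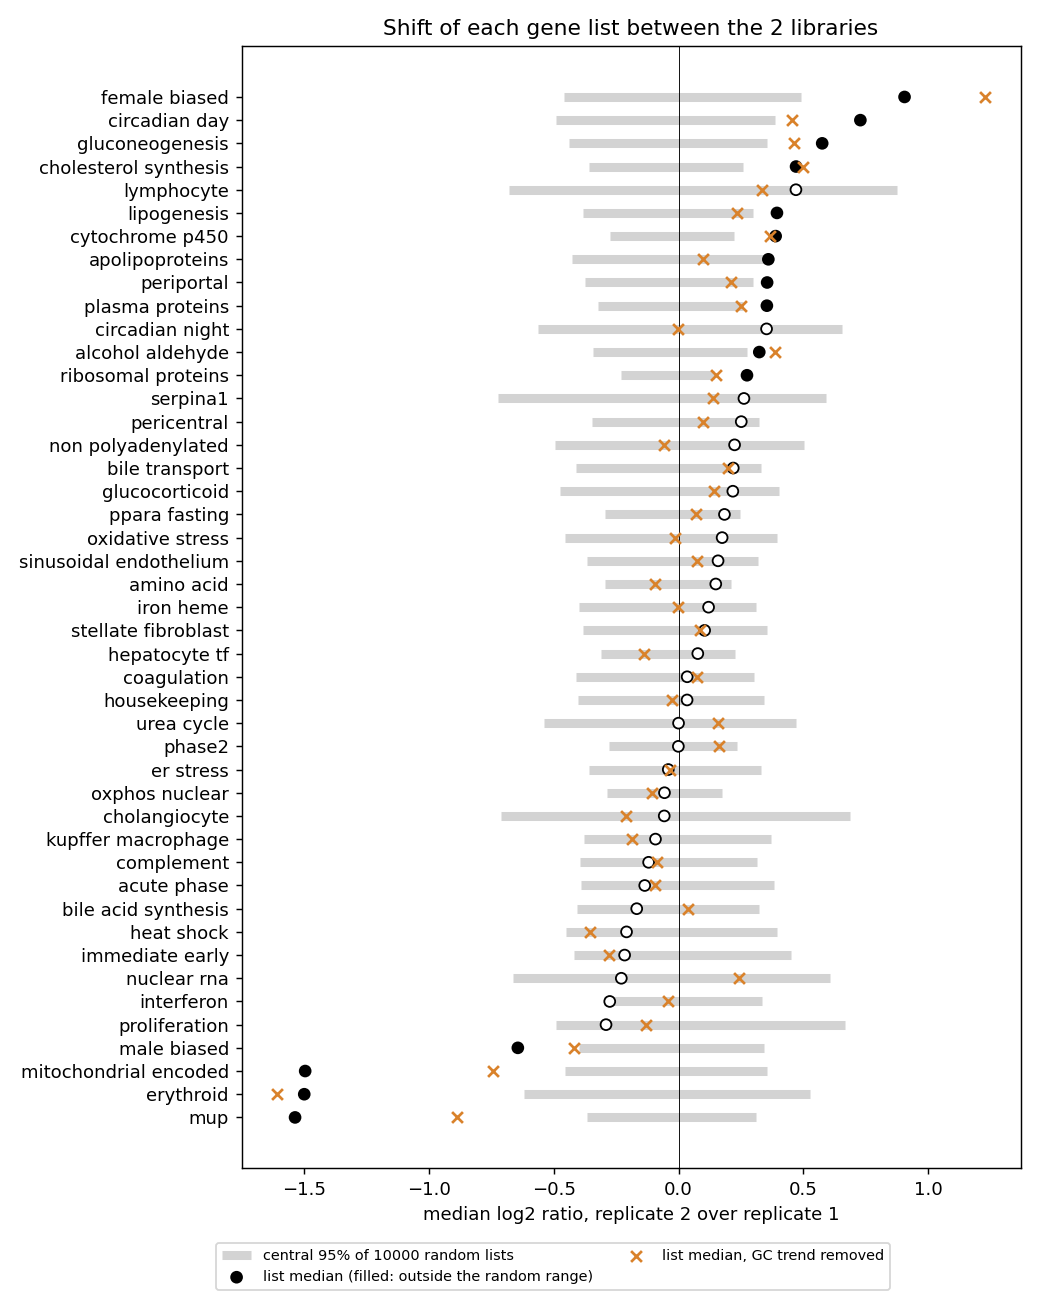
Median log2 ratio of replicate 2 over replicate 1 for each of 45 gene lists (circles, filled where outside the grey bar), the central 95% of 10000 random expression-matched lists without GC correction (grey bars), and the list median with the GC trend removed (orange crosses). Female-biased genes lie highest at 0.90 and the major urinary proteins lowest at -1.54.

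The most abundant transcript of a gene was often not the same in both libraries. Of 7534 genes with at least 2 annotated transcripts, 63.6% had the same top transcript in both libraries (95% Clopper-Pearson interval 62.5 to 64.7%), and the top transcript held a median of 53.996% and 50.2% of its gene's TPM. Spike-in RNA was almost absent although the labels name a spike-in mix: 8 and 10 of the 96 spike-in rows had any count, with 20 and 37 counts in all, a share of 3.32e-04% on average.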

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

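The tests of RNA without a poly(A) tail, of fragment length and of nuclear copies of the mitochondrial genome were chosen after the result was seen, and the length trend itself had been seen before the length test of the sex-biased lists was set. The 26248 rows with numeric identifiers, which no comparison uses, held 1666 counts in replicate 1 and 3722 in replicate 2, above the 3 counts that a count of 0 allows. These were 0.0160% of all counts (95% Clopper-Pearson interval 0.0152 to 0.0168%) and 0.0475% (0.0460 to 0.0491%), on rows with a median length of 73 bases. What these rows hold is not given in the sources used here.

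Small nucleolar RNAs were mostly higher in replicate 2, 90 of 107, with a median log2 ratio of 3.65. A rise of their host genes was argued against: the median difference between a small nucleolar RNA and its host was 3.79, and 88 of 92 lay above their host. Weaker removal of RNA without a poly(A) tail stays open, since the 10 members of that list other than small nucleolar RNAs had a median of 0.21 with an interquartile range from -0.08 to 0.63. Shorter RNA or fragments kept in replicate 2 also stay open. All 27 small nuclear RNAs were higher, whereas of 22 mitochondrial transfer RNAs 15 were lower and 2 higher. The length test cannot decide the question, because it used nuclear protein-coding genes. Their length bins had medians from 641 to 7111 bases, against a median of 130 for small nucleolar RNAs. Across those protein-coding genes Spearman's rho of the log2 ratio on length was -0.12, which alone would have met that test as first written. The test was revised to require the relation after GC correction once the GC trend was seen, and rho was then -0.00840; no biological explanation was tested.

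The medians of the sex-biased lists lay apart: 5 of 11 female-biased genes were higher in replicate 2 and 5 of 17 male-biased genes lower, the others not passing, with a difference of list medians of 1.55 on the log2 scale (95% bootstrap interval over genes 0.94 to 3.67). With the GC trend removed the difference was 1.65 (1.30 to 3.17), and with the length trend removed 1.46 (0.99 to 3.42), which argues against either trend as the whole cause. Among 7 female-biased and 16 male-biased genes with a posterior SD of at most 5% it was 1.40 (0.61 to 1.68). This argues against genes with uncertain counts as the whole cause. It cannot exclude reads shared between paralogs, because genes such as Mup7 and Mup14, whose reads may be split between copies, also pass that limit. No biological explanation was tested, and with 2 libraries of 1 group none can be told from a difference in handling.

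Of 15 mitochondrially encoded mRNAs and rRNAs, 14 were lower in replicate 2. For GC content bias, 826 nuclear protein-coding genes in the GC range of the 13 mitochondrial mRNAs had a median 0.66 above the mitochondrial one (bootstrap interval 0.51 to 0.92). The sets were not matched within that range. The lowest GC bin of nuclear genes had a median of 38.9%. Some mitochondrial mRNAs, such as mt-Atp8 (31.9%) and mt-Nd3 (33.0%), lay well below it, and others, such as mt-Co1 (39.9%), above. The gap can thus come partly from GC content, and whether GC content is the whole cause is not settled. The 826 nuclear genes were themselves at -0.73, against -1.39 for the mitochondrial mRNAs, so GC content may account for at least part of the difference. As the cause of the difference of the whole set, reads moving to nuclear copies were argued against. Mitochondrial genes summed with 7 copies on chromosome 1, picked by hand after 4 were seen, had a log2 ratio of -1.54, and the copies alone -1.48. These sums cannot settle single genes. While mt-Atp6 was 6.65-fold lower, the chromosome 1 pseudogene Gm10925 was 1.48-fold below replicate 1 and did not pass. Part of the mt-Atp6 difference may therefore be reads assigned to copies. No biological explanation was tested.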

How the results depend on the processing

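The alternatives with nuclear protein-coding genes, posterior SD, GC content and the sex-linked check were chosen after seeing the data. No named gene or list that was called in either setting changed direction under the alternatives run, but uncalled values and splits did. The split of 967 higher and 877 lower genes became 594 and 643 in nuclear protein-coding genes and 620 and 628 at a posterior SD of at most 5%. Of 45 list medians, 13 changed sign by the TPM ratio and 11 with the GC trend removed, among them the amino-acid (0.15, then -0.09) and transcription factor (0.08, then -0.14) lists, and 5 list means differed in sign from the median. The complement calls went from 1 lower to 1 higher, in a different gene, with the GC trend removed. The count of called genes, 1844, became 1041 at a mean CPM of at least 5, 3982 with a 1.5-fold and 439 with a 4-fold minimum, and 1057 with the GC trend removed. It stayed within 1.5 times with DESeq2 size factors, total counts, the TPM ratio, no filter, Fisher's exact test, without mitochondrial and the 20 most abundant genes, in nuclear protein-coding genes and at a posterior SD of at most 5%. Genes detected fell to 3431 at a TPM of at least 10, where fewer genes can pass. The nuclear protein-coding share, 56.5% of mouse counts, was 42.2% of TPM and 70.98% without mitochondrially encoded genes. The share of the top 10 genes was 37.2% of expected counts and 35.2% without mitochondrially encoded genes, and 32.4 to 34.4% in single libraries. The top 100 held 64.5% of expected counts. Of the 50 list levels, 37 differed by at least their SD when taken as shares of expected counts, and 13 did not. Pearson's r was 0.767 with a pseudocount of 0.1, 0.647 with 0.01, 0.942 with no filter, 0.745 at a mean TPM of at least 10, 0.942 in nuclear protein-coding genes and 0.939 at a posterior SD of at most 5%. The coefficient of variation was 43.2% by total counts, 39.5% with no filter, 35.9% at a mean CPM of at least 10, 37.995% without mitochondrial and the 20 most abundant genes, 30.1% in nuclear protein-coding genes and 30.9% at a posterior SD of at most 5%. The same top transcript was found for 70.5% of genes at a TPM of at least 10 and 72.3% by expected counts, and the spike-in share of TPM was 8.45e-04%. The cause was not tested for the others. Of the named genes' ratios, 28 lost their call by total counts, 33 by the TPM ratio and 42 with the GC trend removed, and 30, 27 and 8 gained one. Of 15 lists apart, 13 stayed so with the GC trend removed, 13 at a posterior SD of at most 5% and 11 against random lists matched on GC content; 14 did by the TPM ratio, at a mean CPM of at least 5 and with matching on gene length, where the apolipoprotein list fell inside the random range (percentiles 96.03, 97.2 and 97.2), and all 15 with DESeq2 size factors and by list means. Moved outside it were the heat-shock list by the TPM ratio (1.72), the night clock list at a mean CPM of at least 5 (99.97), the list without a poly(A) tail by its mean (99.79) and the interferon list with matching on gene length (2.35). No paired analysis was possible because there was 1 group. With 1 library on each side, depth limits calls of genes near the floor of 3 counts.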

Other observations

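The genes in this part were chosen after their values were seen. Socs2 and Cish, which encode inhibitors of cytokine receptor signalling, were lower in replicate 2, by 8.48-fold (95% counting interval 6.61 to 11.02) and 4.53-fold (95% counting interval 3.60 to 5.76), while Igf1 (392 ± 81.04 TPM) did not pass. Socs2 was at 30.9 and 4.91 TPM and Cish at 11.9 and 3.73 TPM. Among nuclear protein-coding genes with a posterior SD of at most 5%, Mup21, Mup17 and Mup10 were 5.62-fold, 4.79-fold and 4.74-fold lower, although reads may be split between these copies. Rac3, Hsf4 and Zap70 were 11.2-fold, 6.21-fold and 6.85-fold higher, at mean levels of 1.91 ± 2.26, 2.58 ± 2.82 and 1.44 ± 1.59 TPM.

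Processed pseudogenes had 129 higher and 62 lower of 402 tested, and unprocessed pseudogenes 1 higher and 24 lower of 53.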
